A study of Homo sapiens with 8 samples.

How the data were processed

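The data were ChIP-seq peak lists from MCF10A, a line of non-tumorigenic human breast epithelial cells. HP1a (HP1α, encoded by CBX5) and HP1b (HP1β, encoded by CBX1) are paralogous proteins of heterochromatin. There were 8 libraries in 4 groups of 2: HP1a ChIP in wild type, HP1a ChIP in HP1b knockdown, HP1b ChIP in wild type and HP1b ChIP in HP1a knockdown. Per the labels the libraries of a group are replicates 1 and 2, and they are not stated to be separate cultures. Whether replicates of the same number were processed side by side is not stated either.

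The submitters' processing notes name Trimmomatic, Bowtie2, SAMtools, MACS3 and the build hg38. Tool versions, peak-calling settings and the use of an input library are not given in the sources used here. The deposited lists give each broad peak's start and end positions, a score equal to 10 times its −log10 q, its fold enrichment over the local background as a ratio, its −log10 p and its −log10 q. The deposited lists hold no read counts, so read depth is unknown and no counting error, interval or detection floor could be set from it. A place without a peak is one where no peak was listed, which is not the same as an absence of the protein.

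Peaks on chromosomes 1 to 22 and X were used, between 99.1 and 99.7% of each list. Peaks of one list that overlapped were merged when bases were counted. Relative coverage was the number of peak-covered bases in a feature per Mb of all peak-covered bases of the library, which removes a difference in total coverage between libraries. Features were 3043 bins of 1 Mb and 19974 protein-coding genes of RefSeq on GRCh38.p14. The annotation used gives gene bounds only, without strand, exons, repeats or sequence. The promoter windows planned at first were therefore replaced by the gene body with 1 kb on each side, and shares in exons, repeats and GC classes were left out.

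There were 3 comparisons: HP1a ChIP in HP1b knockdown against wild type, HP1b ChIP in HP1a knockdown against wild type, and HP1b ChIP against HP1a ChIP in wild type. The difference between the first and second, called the interaction, was a further test in the bins. Numbers of peaks and covered bases were compared with exact permutation tests, which cannot give a p value below 0.333 for 2 against 2 libraries (two-sided). Bins and gene bodies were fitted with limma (moderated t, variance trend) on log2 of relative coverage plus a pseudocount, the 10th percentile of the values above 0. A feature was fitted if it had a peak in at least 2 of the 4 libraries, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 changes are given with their standard error (SE), and group values as mean ± SD with n = 2. No fold is given against a group listed at 0, because the fitted value then depends on the pseudocount.

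A gene was called lost if both libraries of the first group had a peak in or within 1 kb of it and neither library of the second did. It was called gained in the opposite case, and kept if all 4 libraries had a peak. Regions were those found in both libraries of a group with an overlap of at least 1 base, and chance overlap came from 100 circular shifts. Clustering of changed bins on a chromosome was tested by rotating the calls along the genome.

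The gene lists were C2H2 zinc finger genes, those of them on chromosome 19, clustered protocadherin genes, epithelial and basal genes, mesenchymal genes, TGF-beta and BMP pathway genes, heterochromatin and lamina genes, cohesin, condensin and CTCF genes, olfactory receptor genes, HOX genes, replication-dependent histone genes, ribosomal protein genes, germline and cancer-testis genes, interferon and antiviral genes, liver genes, brain genes and luminal breast genes. Each list's share of lost genes and median log2 change were compared with 10000 random lists of the same size matched on gene length (permutation, two-sided, adjusted over the lists). As an alternative, each list was rotated along the gene order, which keeps neighbouring genes together. Members of a list were also adjusted over the list alone.

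Named genes followed a rule: CBX1, CBX3 and CBX5; the 6 strongest falls and 6 strongest rises past the threshold, or by moderated t where none passed; the 6 lost and 4 gained genes with the highest fold in the weaker of both libraries; up to 3 genes of each list with the highest covered share; and 4 bins in each direction. The comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. Peaks with −log10 q of at least 2, peaks with −log10 p of at least 4, the fit without the distal blocks, unscaled list medians and random lists matched on covered bases were added after the data were seen. The alternatives also took the same number of top peaks from each library, no filter, no scaling, a pseudocount multiplied by 4, all 8 libraries in a single fit, a replicate block, bins of 250 kb, 50% overlap, a flank of 2 kb and each library left out in turn.

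The fits and the list tests are described as tested on simulated data, and planted changes were recovered in bins but hardly ever in single genes. At a planted log2 of 1, 18 and 26% of lower and higher bins were recovered in the HP1a comparison, 80 and 82% in the HP1b comparison and 86 and 96% between the proteins, with 5, 12 and 13 false bin calls. Random subsets of one pool of peaks gave at most 2 calls in 20 draws, which does not test lists cut at different strengths. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.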

Results

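HP1a and HP1b were mapped by ChIP-seq in MCF10A breast epithelial cells, each in wild type and with the other paralog knocked down. The wild-type HP1a lists held 134058 and 115564 peaks on chromosomes 1 to 22 and X, and these covered 69.8 and 60.4 Mb. With HP1b knocked down, the HP1a lists held 19638 and 19092 peaks over 9.89 and 9.68 Mb. The wild-type HP1b lists held 239563 and 240090 peaks over 158.1 and 157.1 Mb. With HP1a knocked down, the HP1b lists held 159536 and 225991 peaks over 118.4 and 164.9 Mb. The lowest −log10 p listed was 3.43 in both HP1a lists from the HP1b knockdown, against 2.75 and 2.80 in wild type, so the lists did not stop at the same strength. In the HP1b lists it was 2.55 and 2.54 in wild type and 2.72 and 2.57 in the HP1a knockdown. The lowest −log10 q was 1.00 in all 8 lists.

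Peaks of a replicate were met by a peak of the other replicate in 18.4 and 21.4% of cases for wild-type HP1a (4.15 and 4.77% after circular shifts). For HP1a with HP1b knocked down the overlap was 6.21 and 6.37% (0.705 and 0.728% after shifts). It was 35.1 and 35.2% for wild-type HP1b (10.4 and 10.3% after shifts) and 48.7 and 34.1% for HP1b with HP1a knocked down (10.9 and 7.67% after shifts). The lower overlap in the HP1b knockdown went with the shorter lists: with the same number of peaks taken from every HP1a library it was 6.00 and 6.04% in wild type and 6.15 and 6.14% in the knockdown. Gene bodies make up 41.6% of the 3029 Mb examined, and they held 39.5 ± 1.53% of wild-type HP1a peak bases (SD, n = 2), 37.9 ± 1.45% with HP1b knocked down (exact permutation p 0.667), 38% of wild-type HP1b peak bases and 34.7% with HP1a knocked down.

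**Figure D1:**
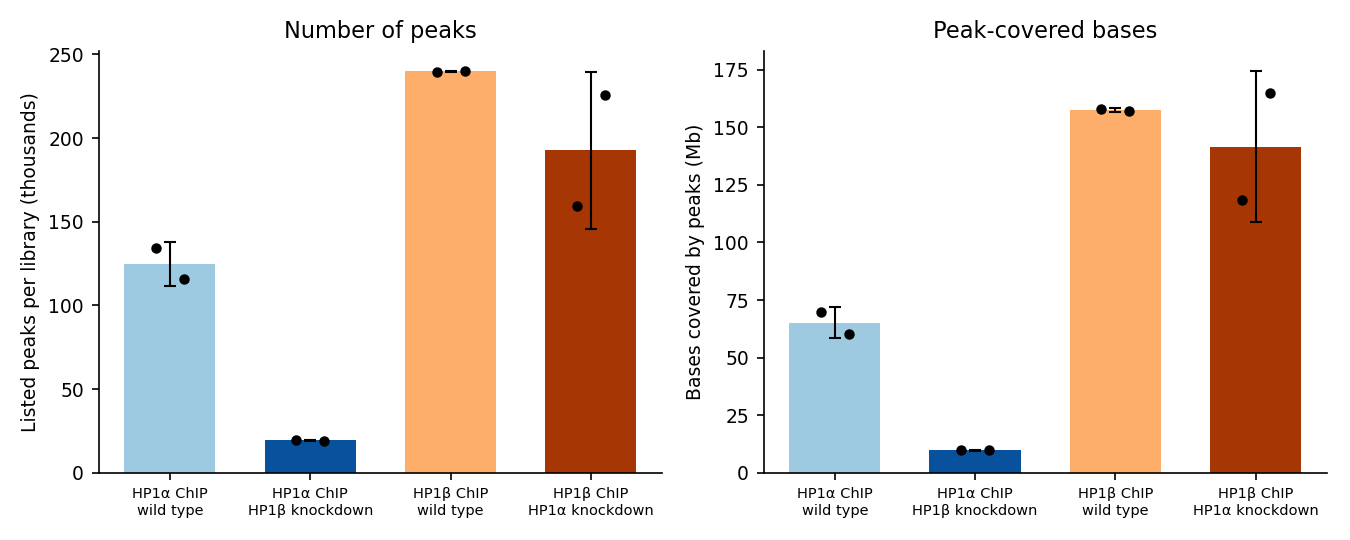
Number of listed peaks (left) and peak-covered bases (right, Mb) per library in the 4 groups, with bars at the mean, error bars for the SD and dots for the 2 libraries. HP1a peaks averaged 124811 in wild type and 19365 with HP1b knocked down, while the HP1b libraries with HP1a knocked down lay far apart, at 159536 and 225991 peaks.

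The first comparison asked whether HP1a occupancy changed when HP1b was knocked down. HP1a peaks were 6.45-fold fewer in the HP1b knockdown, 124811 ± 13077 in wild type and 19365 ± 386 in the knockdown (SD, n = 2 each). Peaks went missing from both knockdown libraries at 3738 of 7945 protein-coding genes that had them in both wild-type libraries (47.0%), among them the keratin gene KRT14, the matrix gene SPARC and the growth factor gene BMP7. This count depends on the shorter knockdown lists: with the same number of peaks per library, lost and gained genes were close in number, with slightly more gained. Chromosome 19 held 2.92 ± 0.0440% of HP1a peak bases in wild type and 6.89 ± 0.228% in the knockdown (SD, n = 2 each), and 6.10 and 6.99% with the same number of peaks per library. C2H2 zinc finger genes and clustered protocadherin genes lost their peaks less often than random genes of the same length, 24.6% against 60.0% and 9.52% against 41.3%. Neighbouring genes of a cluster are not independent, which these random lists do not take into account.

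Covered bases were 6.66-fold fewer, 65.1 ± 6.65 Mb in wild type and 9.78 ± 0.146 Mb in the knockdown (SD, n = 2 each). Median peak width was 446.5 ± 4.95 and 447.5 ± 3.54 bases, so the peaks were fewer and not narrower. The exact permutation p value was 0.333 for the number of peaks and for covered bases, the lowest that 2 against 2 libraries allow. With a single strength required of every list, a −log10 p of at least 4, there were 39514.5 ± 6609 and 10107.5 ± 1128 peaks (3.91-fold fewer). With a −log10 q of at least 2 there were 11518.5 and 295.5, so the size of the difference depended on the strength required while its direction did not.

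Of 24309 wild-type HP1a regions, 11.5% were met by a peak of at least 1 knockdown library. Peaks of both knockdown libraries met 1.49% of them, against 0.101% after circular shifts. In the opposite direction, 54.5% of the 1212 regions found in both knockdown libraries were met in wild type and 45.5% were not. Regions of high wild-type fold were met more often than regions of low fold, from 6.17% in the 10% of regions with the lowest fold to 22.7% in the 10% with the highest. Leaving out either wild-type library lowered the share from 11.5 to 5.36% (replicate 1) or 5.16% (replicate 2), and leaving out a knockdown library lowered it to 6.59% (replicate 1) or 6.43% (replicate 2). Part of this follows from the definition. With a single wild-type library all its peaks count as regions, and with a single knockdown library only its peaks can meet them.

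**Figure D2:**
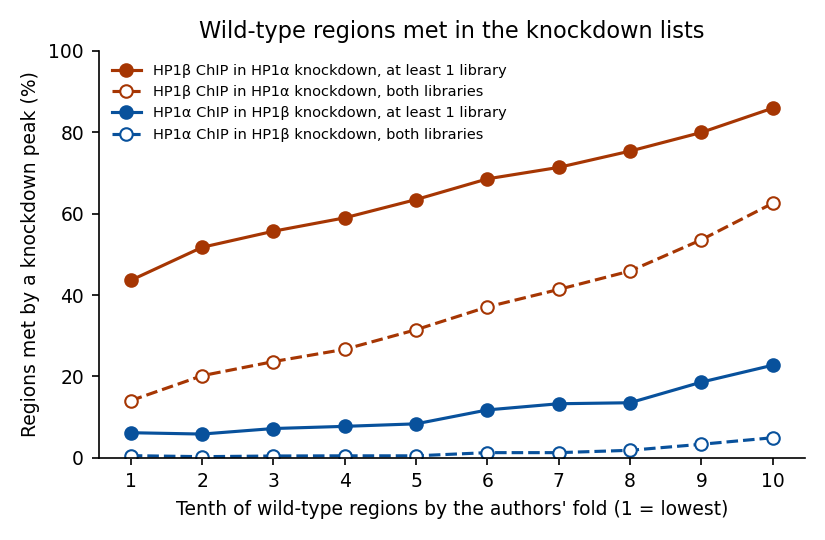
Percent of wild-type regions met by a knockdown peak (vertical) in each 10% of regions ordered by the deposited fold (horizontal, 1 lowest, 10 highest), for HP1a ChIP in HP1b knockdown (blue) and HP1b ChIP in HP1a knockdown (brown). From the lowest to the highest 10% the share in at least 1 library went from 6.17 to 22.7% for HP1a and from 43.6 to 85.9% for HP1b.

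Among single genes, the strongest falls of relative HP1a coverage were at genes listed at 0 in both HP1b-knockdown libraries. In wild type, HP1a peaks covered 8.34 ± 0.338% of GALNT10 (chromosome 5, 154190733 to 154420984), which encodes an enzyme that starts O-linked glycosylation. They covered 5.77 ± 0.665% of EXT1 (chromosome 8, 117794490 to 118111826), which encodes a heparan sulfate polymerase. They covered 3.71 ± 0.706% of FGGY on chromosome 1, a carbohydrate kinase gene, and 5.88 ± 1.48% of the receptor gene LDLRAD3 on chromosome 11. VAT1L on chromosome 16 had 8.84 ± 2.36% and SPIDR on chromosome 8, a DNA repair scaffold gene, 3.17 ± 0.154%. All 6 were listed at 0 in the knockdown, with an adjusted p of 0.024 (limma, n = 2 each). With both knockdown values at 0 these p values depend on the pseudocount, and no gene passed with it multiplied by 4. The same holds for the genes below that were listed at 0 in both libraries of a group.

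Relative HP1a coverage rose most in the HP1b knockdown at 6 genes that had little or none in wild type. SYT3 on chromosome 19, a synaptotagmin gene, went from 0.224 ± 0.317% covered to 6.41 ± 2.34% (log2 5.28, SE 0.64, adjusted p 0.024, limma, n = 2 each). C1orf94 went from 0.939 ± 1.33 to 8.93 ± 3.76% (log2 5.56, SE 0.95, adjusted p 0.0312). The cilium and flagellum genes CFAP77 and CFAP46 went from 0.137 ± 0.194 to 1.34 ± 0.241% (log2 4.91, SE 0.71, adjusted p 0.0249) and from 0.313 ± 0.442 to 2.0 ± 0.568% (log2 4.90, SE 0.88, adjusted p 0.034). The cation channel gene TRPM2 was listed at 0 in wild type and reached 3.88 ± 2.04% (adjusted p 0.024). CRHR1, the receptor gene for corticotropin-releasing hormone, was listed at 0 in wild type and reached 2.83 ± 0.334%.

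The strongest wild-type peaks to go missing lay at TENT5D (deposited fold 5.51 and 4.76 in the 2 libraries), at CYB5R4 and its readthrough RIPPLY2-CYB5R4 (4.75 and 4.68, the same peaks), at the protease gene TASP1 (4.83 and 4.6), at the ubiquitin ligase gene MARCHF1 (4.74 and 4.59) and at FARP1 (4.54 and 5.02). In both knockdown libraries 54 genes gained a peak, among them the muscle gene MYBPC2 (fold 3.62 and 3.65), PIP4P1 (3.74 and 5.43) and RNASEK (4.21 and 4.93). This count too depends on the shorter knockdown lists, since with the same number of peaks per library gained genes outnumbered lost genes. The HP1 genes themselves carried few HP1a peaks. CBX1, the knocked-down gene, was covered over 0.82 ± 1.16% in wild type and listed at 0 in the knockdown, in too few libraries to be tested. CBX3 was listed at 0 in all 4 libraries, and CBX5 had 0.588 ± 0.831 and 0.181 ± 0.256% (adjusted p 0.837, limma, n = 2 each).

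Over all genes with enough peaks, relative HP1a coverage fell at 2475 and rose at 150 of 8504 (limma, n = 2 each, 3574 with unadjusted p under 0.05). Of the falls, 2434 were listed at 0 in both knockdown libraries, and 37 of the rises had no wild-type peak. The median log2 change of all genes was −1.22, and −2.16 without scaling, which gave 51 rises and 4656 falls. No gene passed by limma with the same number of peaks per library, with the pseudocount multiplied by 4, without the filter, or with −log10 p of at least 4 (806, 3338, 2267 and 1614 with unadjusted p under 0.05). With a replicate block 19 genes rose and 0 fell (3786 with unadjusted p under 0.05). Leaving out wild-type replicate 1 gave 26 rises and 2 falls, and replicate 2 gave 24 and 2. Leaving out knockdown replicate 1 gave 851 rises and 2511 falls, and replicate 2 gave 1054 and 2355, with 1244 and 1226 of the falls at the same genes as before. Without wild-type replicate 2 the lost genes numbered 6053, kept genes went from 1723 to 2849 or 3081 without knockdown replicate 1 or 2, and gained genes to between 112 and 408 without any one library. Such counts then rest on the remaining library of a group, so they can only rise.

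The zinc finger genes lost HP1a peaks less often than random genes of the same length when HP1b was knocked down. Of 353 C2H2 zinc finger genes with wild-type peaks, 87 lost them, and of 199 on chromosome 19 only 38 did (19.1% against 63.2% in random lists). Clustered protocadherin genes lost them at 4 of 42. The adjusted permutation p was 0.000867 for each, but it treats neighbouring genes as independent. By rotation along the gene order, which keeps neighbours together, it was 0.0130, 0.0130 and 0.0346. These genes also lost much of their coverage: the mean covered share went from 6.78 ± 0.454 to 1.56 ± 0.0161% for zinc finger genes, from 8.83 ± 0.476 to 1.93 ± 0.0463% for those on chromosome 19 and from 8.50 ± 3.46 to 2.09 ± 1.26% for protocadherin genes (SD, n = 2 each). Against random lists matched on covered bases the shares lost were still 18.4, 22.7 and 14.9 points lower. With −log10 q of at least 2 the zinc finger call ended (adjusted p 0.056) and the protocadherin share lost was 8.72 points above random.

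ZNF134 on chromosome 19 was covered over 47.8 ± 9.24% in wild type and 18.5 ± 8.75% with HP1b knocked down (log2 1.24, adjusted p 0.19, limma, n = 2 each). ZNF7 on chromosome 8 went from 59.1 ± 23.4 to 12.9 ± 4.82%, and ZNF416 from 31.3 ± 0.828 to 13.7 ± 2.98%. ZNF274, whose product recruits a histone methyltransferase to zinc finger gene clusters, went from 32.8 ± 5.17 to 10.9 ± 2.62% (log2 1.10, adjusted p 0.084). ZNF678 on chromosome 1 had 44.7 ± 0.487 and 13.7 ± 1.5%, and its share of all HP1a peak bases rose (log2 1.01, SE 0.13, adjusted p 0.024). Among protocadherin genes, PCDHB5 had 29.4 ± 7.53 and 5.95 ± 8.42%, while PCDHB4 had 22.4 ± 0.613% and was listed at 0 in the knockdown (adjusted p 0.024).

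Scaled gene-body coverage gave the same order of groups with less certainty. The median log2 change was −0.48 for zinc finger genes against −1.06 in random lists (adjusted permutation p 0.0014, rotation 0.0932), −0.42 against −1.01 for those on chromosome 19 (0.00467, rotation 0.179) and 0.71 against −1.26 for protocadherin genes (0.0014, rotation 0.175). For both zinc finger lists the direction turned round without scaling, where they stood 0.00 and −0.24 from random lists, and also without either wild-type replicate. Both passed in the opposite direction with the same number of peaks (−0.52 and −0.76 from random, adjusted p 0.00233 each) and with −log10 q of at least 2 (−0.49 and −0.33, adjusted p 0.004 and 0.0386). Those on chromosome 19 also did with −log10 p of at least 4 (−0.84, adjusted p 0.005) and without wild-type replicate 1 (−0.29, adjusted p 0.0495) or 2 (−0.34, adjusted p 0.024). Over all genes 69 zinc finger genes fell and 10 rose of 373 (59 and 5 adjusted over the list alone), on chromosome 19 36 fell and 4 rose of 208 (30 and 1), and 1 protocadherin gene of 47 fell (0 alone).

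Loss of HP1a peaks at epithelial and mesenchymal genes was not separated from that of random genes. KRT14 was covered over 20.6 ± 10.5% in wild type and listed at 0 in the knockdown (adjusted p 0.0305, limma, n = 2 each), and the desmosome gene PKP1 had 15.1 ± 1.91 and 1.82 ± 2.58%. SPARC had 9.75 ± 2.99% and was listed at 0 (adjusted p 0.0275), and the fibronectin gene FN1 had 4.7 ± 2.77 and 0.129 ± 0.182% (adjusted p 0.227). Epithelial and basal genes lost peaks at 8 of 12 (66.7% against 48.5% in random lists) and mesenchymal genes at 9 of 14 (64.3% against 48%, adjusted permutation p 0.577 each), with 95% of random lists between 25 and 75% and between 21.4 and 71.4%. Of epithelial genes 6 of 12 fell in coverage (6 adjusted over the list alone), and of mesenchymal genes 7 of 13 (8 alone).

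In the TGF-beta and BMP pathway, TGFB2 had 12.6 ± 2.41% covered by HP1a in wild type and 0.314 ± 0.444% in the knockdown (log2 −3.41, adjusted p 0.208, limma, n = 2 each). BMP7 had 4.74 ± 1.89% and was listed at 0 (adjusted p 0.0271). The list lost peaks at 11 of 24 genes, 45.8% against 44.4% in random lists (adjusted permutation p 1), and 7 of 25 fell (7 adjusted over the list alone). Its mean covered share was 1.94 ± 0.0405 and 0.139 ± 0.0290%. Among heterochromatin and lamina genes 7 of 14 lost peaks and 4 of 14 fell (4 alone), and LMNA had 2.85 and 0.591% (adjusted p 0.853). Among cohesin, condensin and CTCF genes 6 of 10 lost peaks and 4 of 12 fell (4 alone), including the cohesin subunit gene SMC1A, 2.85 ± 0.392% in wild type and listed at 0 in the knockdown (adjusted p 0.024), and PDS5B, 2.46 ± 0.991% and listed at 0 (adjusted p 0.0271).

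Of olfactory receptor genes 20 of 40 lost HP1a peaks against 66.8% in random lists (adjusted permutation p 0.0929), and 14 of 47 fell (14 adjusted over the list alone). OR4C46 was covered over 58.9 ± 3.27% and OR2AK2 over 55.8 ± 11.3% in wild type, and both were listed at 0 in the knockdown (adjusted p 0.024 and 0.0246, limma, n = 2 each). Interferon and antiviral genes lost peaks at 8 of 9 (adjusted p 0.577) and 5 of 8 fell (5 alone), among them IFIT2, 6.66 ± 1.92% and listed at 0, and OAS2, 3.83 ± 0.141% and listed at 0 (adjusted p 0.024 each). Germline and cancer-testis genes lost peaks at 8 of 14 and 6 of 14 fell (6 alone), with MAGEC1 at 19.1 ± 2.32% and listed at 0. Brain genes lost peaks at 5 of 18, with 5 down and 2 up of 19 (the same alone). The splicing factor gene RBFOX1 had 4.58 ± 0.607 and 2.46 ± 0.203%, so that its share of HP1a peak bases rose (log2 1.83, SE 0.20, adjusted p 0.024). HOX genes lost peaks at 1 of 2, histone genes at 1 of 1, ribosomal protein genes at 4 of 5, liver genes at 0 of 3 and luminal breast genes at 2 of 4, and no member of these lists passed by limma.

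**Figure D3:**
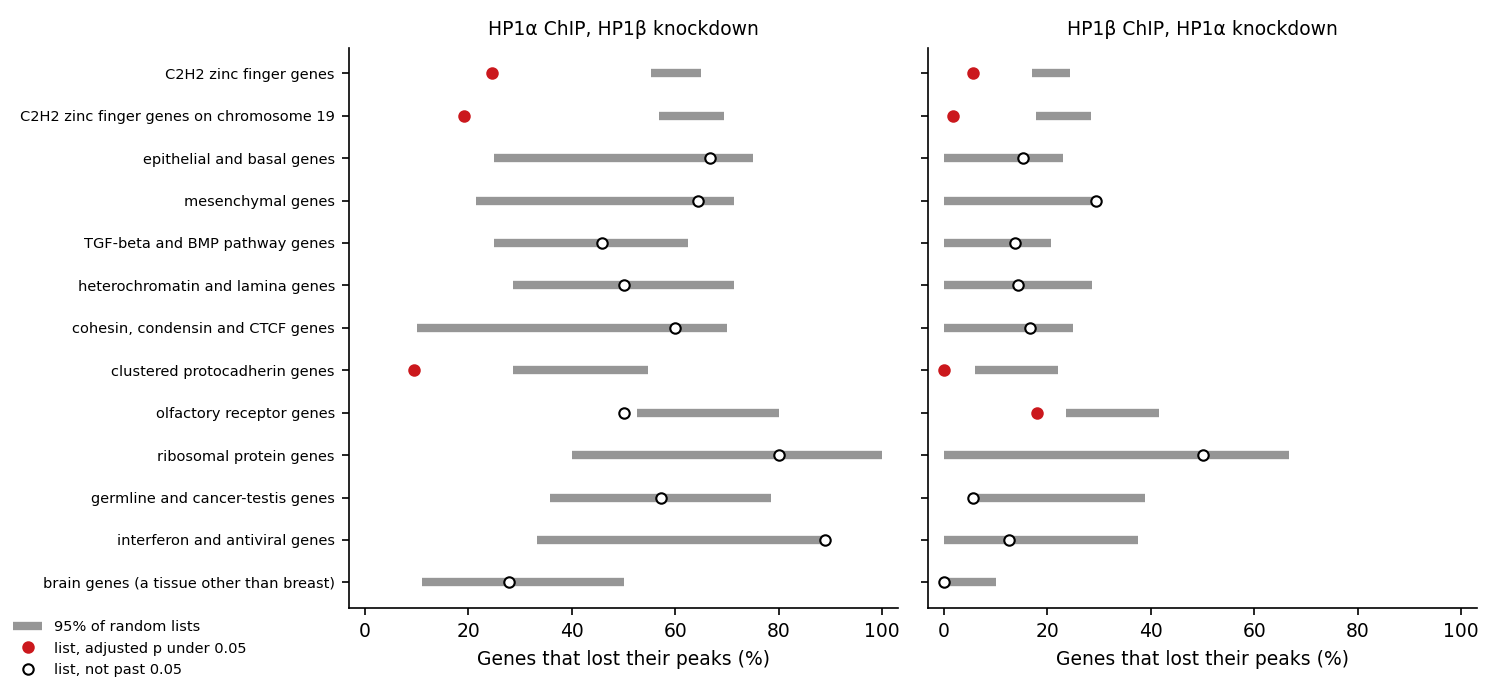
Percent of genes with wild-type peaks that lost them in both knockdown libraries (horizontal) for each gene list (vertical), HP1a ChIP in HP1b knockdown on the left and HP1b ChIP in HP1a knockdown on the right; grey bars span 95% of random lists matched on gene length. Zinc finger genes lost peaks at 24.6% against 60.0% in random lists on the left and at 5.69% against 20.8% on the right.

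Along the chromosomes, the largest fitted fall in the share of HP1a peak bases was around MYC. The bin at 127 to 128 Mb of chromosome 8, with MYC and POU5F1B, was covered over 9.98 and 7.61% in wild type and 0.103 and 0.237% in the HP1b knockdown (log2 −2.51, SE 0.31, adjusted p 0.00474, limma, n = 2 each). The share also fell at 60 to 61 Mb of chromosome 3 within FHIT (log2 −2.46, SE 0.34, adjusted p 0.00644), at 130 to 131 Mb of chromosome 8 with ASAP1 and ADCY8 (−2.27, SE 0.25, 0.00363) and at 116 to 117 Mb of chromosome 9 with PAPPA and ASTN2 (−2.21, SE 0.42, 0.0199). The FHIT bin went from 2.73 and 2.96% covered to 0 and 0.0208%, and the PAPPA bin from 2.96 and 3.16% to 0 and 0.0815%. So near 0 the fitted log2, and with it the order of these bins, depends on the pseudocount. The largest fitted rise was at 2 to 3 Mb of chromosome 2 over MYT1L, a neuronal transcription factor gene (log2 3.06, SE 0.26, adjusted p 0.00211). Its coverage went from 1.24 and 0.674 to 1.62 and 1.93%. With −log10 q of at least 2 this bin turned round past the threshold (log2 −1.8, adjusted p 0.00866). Further rises were at 63 to 64 Mb of chromosome 20 with the acetylcholine receptor gene CHRNA4 (2.77, SE 0.35, 0.00483), at 70 to 71 Mb of chromosome 11 with SHANK2 and CTTN (2.73, SE 0.19, 0.00211) and at 142 to 143 Mb of chromosome 8 with ADGRB1 and ARC (2.72, SE 0.17, 0.00211). The last was covered over 8.27 and 7.11% in wild type and 8.07 and 8.1% in the knockdown, a region that kept its coverage while most others lost it. Both chromosome 8 falls and this rise lie in the distal block from 99 Mb, for which extra copies are weighed below. The distal blocks of chromosomes 1, 5 and 8 together held 21.2 and 19.3% of HP1a peak bases in wild type and 15.4 and 15.0% in the knockdown. With these blocks left out of the fit 165 bins fell, 149 of them the same bins.

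Of 2878 bins, 209 rose and 217 fell in relative HP1a coverage (limma, n = 2 each), with a median log2 change of −0.34 over all bins and −2.62 without scaling. With the same number of peaks per library 130 rose and 86 fell, of which 113 and 38 were the same bins, and without scaling 4 rose and 2736 fell. On chromosome 19, 33 of 57 bins rose and 0 fell, against 176 rises in 2821 bins elsewhere (adjusted rotation p 0.0115, permutation). The chromosome's 2.36-fold higher share of peak bases had an exact p of 0.333 (n = 2 each), and with the same number of peaks the gap shrank from 3.96 to 0.887 points. The share held by its zinc finger genes went from 0.924 to 1.33%. Chromosome shares also rose without overlap of the groups on chromosomes 22 (1.28 to 2.19%), 16 (2.68 to 4.18%) and 17 (2.04 to 3.15%), among others. They fell on chromosome 1 (14.0 to 10.4%) and some others. On chromosomes 16 and 22, 17 of 82 and 7 of 40 bins rose (adjusted rotation p 0.345 and 0.757, permutation). With −log10 p of at least 4 only 7 bins rose and 0 fell. With −log10 q of at least 2, 15 rose and 1653 fell, and 66 of the 209 rises turned into falls. Leaving out wild-type replicate 1 gave 120 rises and 18 falls, replicate 2 118 and 25, knockdown replicate 1 480 and 1059, and knockdown replicate 2 511 and 1054.

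**Figure D4:**
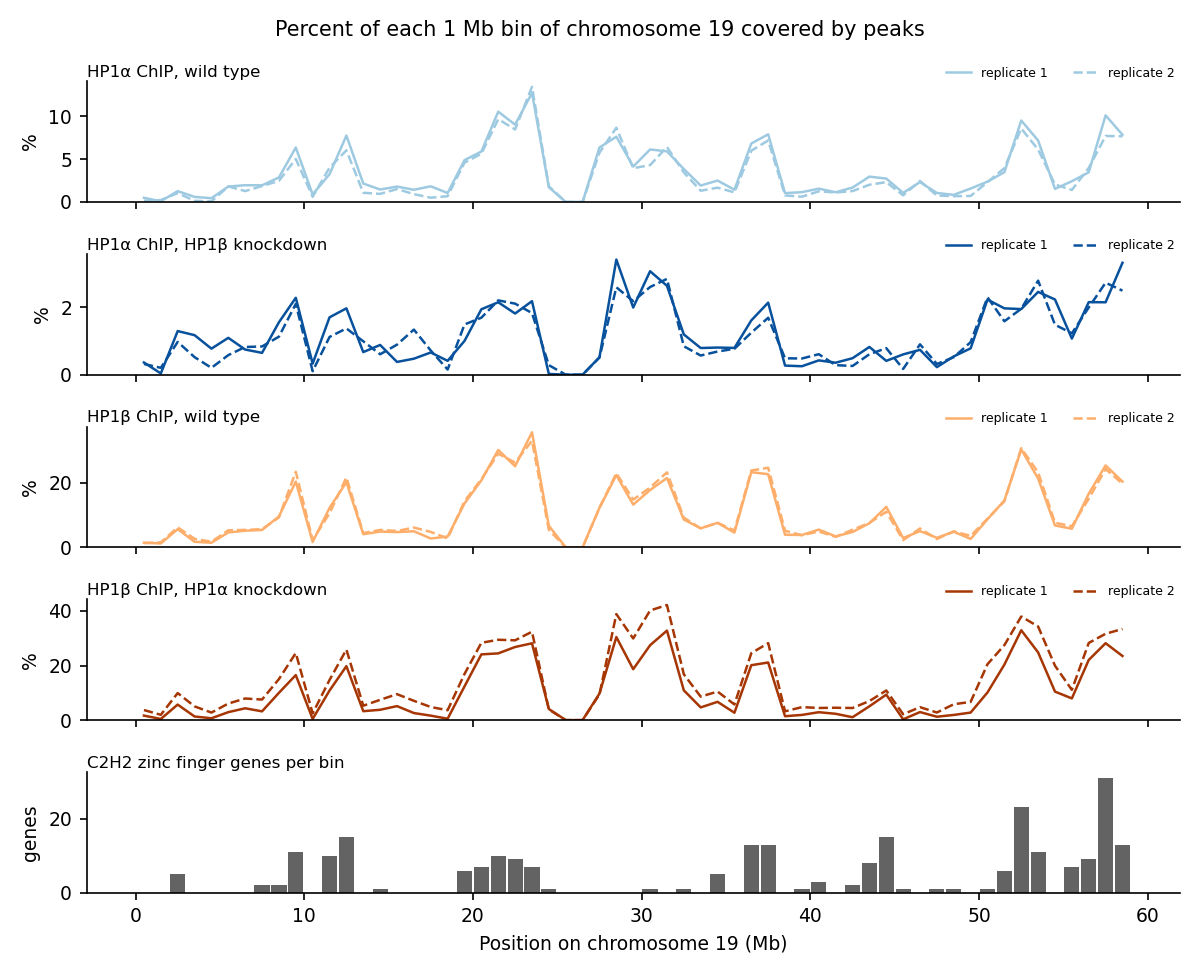
Percent of each 1 Mb bin covered by peaks (vertical, its own scale in each row) along chromosome 19 (horizontal, Mb) for both replicates of the 4 groups, with the number of C2H2 zinc finger genes per bin in the bottom row. Peaks lay over the zinc finger gene clusters in all groups, and chromosome 19 held 2.92% of HP1a peak bases in wild type and 6.89% with HP1b knocked down (6.10 and 6.99% with the same number of peaks).

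The second comparison asked the converse, whether HP1b occupancy changed when HP1a was knocked down. Of 11100 genes with HP1b peaks in wild type, 7055 had a peak in both knockdown libraries too (63.6%), and 1572 had none in either (14.2%). Of single HP1b regions, 35.6% were met in both knockdown libraries and 34.6% in neither. Relative HP1b coverage fell most in bins around LMNA, CEBPB and SNAI1 and rose most in the bins of MYT1L, NPHP4, NTM and TMEM132D. The bin over MYT1L went from 3.78 and 2.8% covered in wild type to 20 and 28.8% in the knockdown, and the bin over LMNA from 5.87 and 11.5 to 0.467 and 2.1%. Of 2891 bins, 204 rose and 348 fell in relative HP1b coverage (limma, n = 2 each).

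HP1b peaks numbered 239826 ± 373 in wild type and 192764 ± 46991 in the HP1a knockdown (SD, n = 2 each), a ratio of 0.804 with an exact permutation p of 0.333, the lowest possible. Covered bases were 157.6 ± 0.771 and 141.6 ± 32.9 Mb, a ratio of 0.899 with overlapping groups (exact p 1), and without knockdown replicate 1 the ratio was 1.05. Median width was 531.5 ± 2.12 and 563 ± 14.1 bases. With −log10 p of at least 4 the direction turned round, 34874 and 48426 peaks. Of 81252 wild-type regions, 65.4% were met by at least 1 knockdown library, and the share met by both was 5.76% after shifts. Leaving out wild-type replicate 1 or 2 lowered the 65.4% to 43.6 or 42.9%, and knockdown replicate 1 or 2 to 55.0 or 46.1%. As for HP1a, part of this follows from the definition of regions.

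The falls with the largest moderated t at single genes did not pass the threshold, and their values are given as such (adjusted p 0.141 each, limma, n = 2 each). HP1b covered 9.72 ± 0.115% of CTIF on chromosome 18, a translation initiation gene, in wild type and 1.73 ± 0.428% with HP1a knocked down (log2 −2.28, SE 0.22). MGAT5, a glycosyltransferase gene on chromosome 2, had 8.41 ± 0.517 and 1.14 ± 0.0845% (−2.62, SE 0.26), and LDLRAD3 13.2 ± 0.0243 and 2.03 ± 0.069% (−2.47, SE 0.24). The formin gene FHOD3 had 9.47 ± 1.35 and 2.13 ± 0.514% (−1.96, SE 0.21), SYN3 14.3 ± 1.46 and 4.28 ± 1.24% (−1.58, SE 0.18) and THSD4 9.54 ± 0.738 and 2.39 ± 0.973% (−1.87, SE 0.21).

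The rises with the largest moderated t did not pass the threshold either (adjusted p 0.141 each, limma, n = 2 each). MYT1L (chromosome 2, 1789113 to 2331275) had 1.65 ± 0.254% in wild type and 12.3 ± 2.91% in the HP1a knockdown (log2 3.02, SE 0.20). The synaptic gene RIMBP2 (chromosome 12, 130396133 to 130716299) had 4.23 ± 0.975 and 32.1 ± 9.5% (3.05, SE 0.23). The ephrin receptor gene EPHB1 had 8.14 ± 0.229 and 26.1 ± 5.34% (1.83, SE 0.15), DPP6 7.17 ± 0.85 and 24.4 ± 3.96% (1.93, SE 0.16), the synaptic scaffold gene SHANK2 11.8 ± 1.21 and 41.0 ± 13.2% (1.93, SE 0.16) and GLT1D1 9.97 ± 0.551 and 39.0 ± 7.84% (2.10, SE 0.18). RBFOX1 had 19.3 ± 0.628 and 31.8 ± 0.872% (0.90).

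The strongest peaks to go missing lay at the amino acid transporter gene SLC3A2 (deposited fold 3.71 and 4.46), KLHL28 (4.16 and 3.90), RNF216 (3.90 and 3.68) and over DDIT3, MBD6 and LOC128125814, which shared a single peak (4.88 and 3.67). Gained peaks, at 205 genes, were led by SCART1 (3.73 and 3.51), the lectin genes CLEC5A (4.53 and 3.34) and CLEC6A (3.31 and 3.26) and the meiosis gene SYCE1 (3.29 and 3.14). CBX1 had 4.49 ± 3.51% covered by HP1b in wild type and 0.278 ± 0.394% in the knockdown (log2 −1.91, SE 0.74, adjusted p 0.201, limma, n = 2 each). CBX3 had 0.715% and was listed at 0, and CBX5, the knocked-down gene, had 0.68 and 1.03% (adjusted p 0.932).

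By limma 0 of 12363 genes passed in either direction (n = 2 each), while 3065 had an unadjusted p under 0.05 and the smallest adjusted p was 0.141. With a replicate block 121 were higher and 281 lower, and in the fit of all 8 libraries 66 and 189. With 1 library left out some passed too: 75 up and 124 down without wild-type replicate 1, 72 and 75 without replicate 2, 210 and 620 without knockdown replicate 1, and 257 and 1753 without knockdown replicate 2. Lost genes then numbered 2824 and 2531 without wild-type replicates 1 and 2 and 3721 without knockdown replicate 2, against 1572 with all. Gained genes went from 205 to between 353 and 885. Lost and gained genes then rest on the remaining library of a group, so these counts can only rise.

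Zinc finger genes lost HP1b peaks less often than random genes when HP1a was knocked down, 24 of 422 (5.69% against 20.8%) and 4 of 225 on chromosome 19 (1.78% against 23%), with an adjusted permutation p of 0.0016 each and 0.016 by rotation. Clustered protocadherin genes lost them at 0 of 50 against 13.9% (0.00213, rotation 0.192), and olfactory receptor genes at 16 of 89, 18.0% against 32.9% (0.004, rotation 0.706). Against random lists matched on covered bases 0 of the lists passed. The mean covered share was 20.4 ± 0.411 and 19.2 ± 1.8% for zinc finger genes, and 13.7 ± 0.178 and 20.7 ± 4.32% for protocadherin genes (SD, n = 2 each). ZNF134 had 84.0 ± 6.17 and 63.2 ± 5.13%, ZNF274 60.2 ± 6.5 and 73.4 ± 9.61%, and PCDHB11 32.4 ± 20.7 and 58.6 ± 20.1%.

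The change of relative HP1b coverage at HOX genes as a group was lower than at random genes, a call that ended by rotation (adjusted p 0.116) and without knockdown replicate 2 (0.071). HOXA7 had 20.9 ± 8.62%, HOXA11 18.8 ± 3.04% and HOXA4 17.7 ± 14.2% in wild type, and all 3 were listed at 0 in the HP1a knockdown. The list's mean covered share was 3.88 ± 1.00 and 0.806 ± 0.181% (SD, n = 2 each) and its median log2 change −1.47 against −0.20 in random lists (adjusted permutation p 0.00427), with peaks lost at 6 of 9 (adjusted p 0.179). Medians above those of random lists were found for protocadherin genes (0.71 against −0.37, adjusted p 0.0008, rotation 0.0256), olfactory receptor genes (0.32 against −0.15, 0.0008, rotation 0.016), germline and cancer-testis genes (0.56 against −0.45, 0.00192, rotation 0.0213), brain genes (0.29 against −0.41, 0.0096, rotation 0.0256), zinc finger genes (−0.01 against −0.50, 0.0008, rotation 0.016) and those on chromosome 19 (0.05 against −0.50, 0.0008, rotation 0.0266). With −log10 p of at least 4 both zinc finger lists turned round and passed the other way (−0.25 and −0.42 from random, adjusted p 0.004 each). Without knockdown replicate 1 the call ended for both zinc finger lists (adjusted p 0.075 and 0.098) and the germline list (0.075), without wild-type replicate 1 for the germline list (0.25) and without wild-type replicate 2 for olfactory receptor genes (0.075).

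Over all genes 0 members of any list passed by limma, with 3065 of all genes at an unadjusted p under 0.05. Adjusted over the list alone, 14 of 52 protocadherin genes rose, 5 of 11 HOX genes fell, 3 of 21 brain genes and 1 of 3 histone genes rose, and 0 members of the other lists passed. Peaks were lost at 2 of 13 epithelial and basal genes, 5 of 17 mesenchymal genes, 4 of 29 TGF-beta and BMP pathway genes, 2 of 14 heterochromatin and lamina genes, 2 of 12 cohesin, condensin and CTCF genes, 3 of 6 ribosomal protein genes, 1 of 18 germline genes, 2 of 16 interferon and antiviral genes, 3 of 10 liver genes, 0 of 20 brain genes, 3 of 9 luminal breast genes and 0 of 0 histone genes, none past the threshold. TGFB2 had 15.5 ± 0.777 and 3.36 ± 3.58% (adjusted p 0.148, limma, n = 2 each), SMAD6 12.9 ± 1.22 and 3.43 ± 2.72%, PKP1 26.3 ± 7.17 and 5.53 ± 4.83%, TGFBI 10.6 ± 6.49% and 0, and SNAI1 15.0 ± 17.2% and 0.

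In the bins, relative HP1b coverage fell at 156 to 157 Mb of chromosome 1 with LMNA and MEF2D (log2 −1.68, SE 0.27, adjusted p 0.00434, limma, n = 2 each). It fell over neighbouring bins of chromosome 20, at 50 to 51 Mb with CEBPB and PTPN1 (−1.49, SE 0.21, 0.00211) and at 49 to 50 Mb with SNAI1 (−1.48, SE 0.16, 0.000326), and at 149 to 150 Mb of chromosome 5 with CSNK1A1 and PPARGC1B (−1.34, SE 0.18, 0.00138). It rose at 2 to 3 Mb of chromosome 2 with MYT1L (2.47, SE 0.15, 3.83e-05), at 5 to 6 Mb of chromosome 1 with NPHP4 and KCNAB2 (2.04, SE 0.14, 6.61e-05), at 131 to 132 Mb of chromosome 11 with NTM (2.01, SE 0.17, 8.22e-05) and at 129 to 130 Mb of chromosome 12 with TMEM132D (1.97, SE 0.18, 0.000136). On chromosome 20, 31 of 64 bins fell (rotation p 0.0045, adjusted 0.103) and its share of peak bases went from 3.00 ± 0.0336 to 2.44 ± 0.0610%. On chromosome 19, 14 of 57 bins rose (adjusted rotation p 0.862), and its share went from 3.91 ± 0.0953 to 5.14 ± 0.0492% but turned round with −log10 p of at least 4 (−0.933 points).

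The median log2 change over all bins was −0.10, and −0.21 without scaling, where 49 bins rose and 51 fell. With the same number of peaks 249 rose and 445 fell, with −log10 p of at least 4 93 and 67, and with −log10 q of at least 2 1 and 0. Leaving out wild-type replicate 1 gave 76 rises and 72 falls, replicate 2 55 and 20, knockdown replicate 1 324 and 534, and knockdown replicate 2 438 and 839.

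Relative coverage, scaled to each library total, changed in the same direction at many regions in both knockdowns. Of 2878 bins, 116 rose in both comparisons where 14.8 were expected by chance, the bin of MYT1L among them (turned round for HP1a with −log10 q of at least 2, log2 −1.8), and 74 fell in both where 26.2 were expected. The rotation p was 0.0001 for each, the smallest that 10000 rotations allow (permutation). No bin passed in opposite directions. All this holds for scaled coverage: without scaling 4 HP1a bins rose and 2736 fell, with 113 of the 209 rises turned into falls, while 49 HP1b bins rose and 51 fell. With −log10 p of at least 4 only 7 bins rose and 0 fell for HP1a by limma (665 with unadjusted p under 0.05), so no shared fall and at most 7 shared rises held there. With −log10 q of at least 2, 66 of the 209 HP1a rises turned into falls and 5 stayed rises. For HP1b 1 bin rose and 0 fell there by limma (337 with unadjusted p under 0.05). The log2 changes had a Pearson correlation of 0.548 and a Spearman correlation of 0.413 across bins, which are not independent replicates, and the highest Pearson value among rotations was 0.268. In the interaction test, 2 of 2891 bins were higher and 1 lower in the HP1a comparison (limma, 2 libraries in each of 4 groups, 678 with unadjusted p under 0.05), so a difference between both knockdown effects was seen at 3 places only. Without scaling the interaction gave 0 higher and 2504 lower. It gave 298 higher and 537 lower without HP1a knockdown replicate 1, 329 and 577 without replicate 2, and 0 or 1 without any other library.

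The last comparison set HP1b against HP1a in wild-type cells. HP1b had 1.92 times as many peaks as HP1a and 2.42 times the covered bases, and its median peak was wider, 531.5 ± 2.12 against 446.5 ± 4.95 bases (SD, n = 2 each). HP1b peaks were found at 7308 of 7945 genes with HP1a peaks (92.0%), and 117 had HP1a without HP1b. Over all genes, 11100 of 19974 had HP1b peaks in both libraries, and the 92.0% was not set against genes of the same length. Relative coverage of HP1b was lower over the distal parts of chromosomes 1, 5 and 8, around KIF26B, KCNH1 and ESRRG, and higher at NELL1, CDH11 and STXBP6. Of 2888 bins, 110 were higher and 155 lower in HP1b (limma, n = 2 each), and none with −log10 p of at least 4, without the filter or with all 8 libraries (315, 534 and 244 with unadjusted p under 0.05).

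The number of peaks had an exact permutation p of 0.333, the lowest possible, and with −log10 p of at least 4 the ratio was 0.883, the other way round. HP1b met 76.1% of 24309 HP1a regions in at least 1 library and 42.7% in both, against 5.28% after shifts. HP1a met 49.7% of HP1b regions in at least 1 library and 15.3% in both, against 1.92% after shifts. Leaving out HP1a replicate 1 or 2 lowered the 76.1% to 52.9 or 50.6%, and HP1b replicate 1 or 2 to 60.8 or 58.0%. The 117 genes with HP1a alone went to 412 and 611 without HP1a replicates 1 and 2, and to 314 and 440 without HP1b replicates 1 and 2, and the 1326 genes with HP1b alone to between 2235 and 2883. These shifts again follow in part from the definitions, since presence then rests on the remaining library of a group.

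At single genes none passed, and the following had the largest moderated t (adjusted p 0.344 or more, limma, n = 2 each). HP1a against HP1b coverage was 12.1 ± 2.68 and 10.4 ± 0.505% at the kinesin gene KIF26B (log2 −1.47, SE 0.18), 6.13 and 4.91% at ASTN1 (−1.57), 5.09 and 4.63% at the potassium channel gene KCNH1 (−1.40), 7.37 and 4.65% at NVL (−1.86), 1.22 and 1.13% at GALNTL6 (−1.36) and 4.93 and 5.20% at ESRRG (−1.19). In the other direction it was 2.0 ± 0.0224 and 23 ± 0.934% at the imprinted gene ZIM2 (2.11, SE 0.32), 2.78 ± 0.736 and 27.0 ± 3.53% at ZFP14 (1.88, SE 0.36), 1.24 and 8.53% at NELL1 (1.5, SE 0.28), 1.53 and 13.2% at TBL1X (1.79), 2.01 and 10.1% at NUBPL (1.04) and 0.366 and 6.15% at LOC124902894 (2.46). HP1a peaks without HP1b were strongest at MMP10, DEFB110, CD22, CXCL5, CCDC39 and OR2T6, and HP1b peaks without HP1a at KLHL28, PCDHB14, FEZ1 and SLC3A2. CBX1 had 0.82 ± 1.16 and 4.49 ± 3.51% (adjusted p 0.791), CBX3 0 and 0.715%, and CBX5 0.588 and 0.68%.

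By limma 0 of 12350 genes passed either way, with 1587 at an unadjusted p under 0.05, and the median log2 difference was 0.09, or 0.96 without scaling. Without HP1a replicate 1 there were 195 higher and 80 lower, without replicate 2 141 and 172, without HP1b replicate 1 1 and 1, and without HP1b replicate 2 1 and 8. Members of every list gave 0 calls, over all genes and adjusted over the list alone, with those 1587 unadjusted over all genes.

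Of 353 zinc finger genes with HP1a, 349 had HP1b peaks in both HP1b libraries and 0 lacked them in both, against 2.78% in random lists (adjusted permutation p 0.0026, rotation 0.0519) and 0 of 199 on chromosome 19 against 3.15% (0.0169, rotation 0.240), and neither held against lists matched on covered bases. ZNF134 was covered over 47.8 ± 9.24% by HP1a and 84.0 ± 6.17% by HP1b, ZNF551 over 36.2 and 68.2%, ZNF549 over 40.7 and 61.5% and ZNF7 over 59.1 and 77.2%. The clustered protocadherin genes lie in the distal block of chromosome 5 from 119 Mb, set off below by lower HP1b than HP1a values. Their median is therefore not separate from that block. The median log2 difference was 0.42 against 0.16 for zinc finger genes (adjusted p 0.0016, rotation 0.032), 0.47 against 0.19 for those on chromosome 19 (0.0096, rotation 0.115), −0.48 against 0.08 for epithelial and basal genes (0.0403, rotation 0.0746), −0.68 against 0.03 for protocadherin genes (0.0016, rotation 0.144) and −1.33 against 0.24 for ribosomal protein genes (0.00213, rotation 0.032). Of these, the zinc finger calls ended without HP1a replicate 1 (adjusted p 0.45 and 0.62), as did the protocadherin call (0.08), and the ribosomal value turned round (0.84 above random). The epithelial call ended without any one library (0.62 and 0.38 without HP1a replicates 1 and 2, 0.21 and 0.24 without HP1b replicates 1 and 2), and the ribosomal call without HP1a replicate 2 (0.86).

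HP1b was missing at 1 of 12 epithelial genes, 3 of 40 olfactory receptor genes, 2 of 5 ribosomal protein genes, 1 of 2 HOX genes and 1 of 1 histone genes with HP1a, and at 0 of the mesenchymal, TGF-beta and BMP pathway, heterochromatin and lamina, cohesin, condensin and CTCF, protocadherin, germline, interferon and antiviral, liver, brain and luminal breast genes. KRT14 had 20.6% covered by HP1a and 31.1% by HP1b, PKP1 15.1 and 26.3%, TGFB2 12.6 and 15.5%, SMAD6 2.74 and 12.9%, SUV39H1 2.8 and 8.18%, ATRX 2.41 and 8.28%, PCDHB5 29.4 and 41.3%, RBFOX1 4.58 and 19.3%, SYN1 6.57 and 22.3% and GRIN2A 3.61 and 15.9%. SPARC had 9.75 ± 2.99 and 4.99 ± 0.411% (adjusted p 0.344, limma, n = 2 each). FST, HOXD10, RPL26L1 and MAGEA10 also had the higher mean by HP1a, with overlapping libraries.

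In the bins, HP1b relative to HP1a was lowest on distal chromosome 1, at 245 to 246 Mb with KIF26B and SMYD3 (log2 −1.14, SE 0.15), 210 to 211 Mb with KCNH1 and HHAT (−1.04, SE 0.14), 216 to 217 Mb with ESRRG (−0.95, SE 0.14) and 176 to 177 Mb with PAPPA2 and ASTN1 (−0.95, SE 0.14), all with an adjusted p of 0.00157 (limma, n = 2 each). It was highest at 21 to 22 Mb of chromosome 11 with NELL1 (1.01, SE 0.17, 0.00306), 65 to 66 Mb of chromosome 16 with CDH11 (0.91, SE 0.17, 0.00551), 25 to 26 Mb of chromosome 14 with STXBP6 (0.87, SE 0.14, 0.00261) and 48 to 49 Mb of chromosome 19 with LIG1 and EMP3 (0.85, SE 0.15, 0.00393). Chromosome 1 held 82 of the 155 lower bins among its 229 (adjusted rotation p 0.908), and 14.0 ± 0.782% of HP1a against 9.68 ± 0.781% of HP1b peak bases. On chromosome 19, 21 of 57 bins were higher in HP1b (adjusted rotation p 0.0460).

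Most of the lower bins, 82, 39 and 25 of 155, lay on chromosomes 1, 5 and 8, though clustering on a chromosome did not pass there (adjusted rotation p 0.908, 1 and 1). After the data were seen, each chromosome was split where the wild-type HP1b minus HP1a difference itself best divided its bins. The strongest splits set off 3 distal blocks, from 147 Mb of chromosome 1, 119 Mb of chromosome 5 and 99 Mb of chromosome 8 to the chromosome ends. These 212 bins make up 6.95% of the sequence examined and held 21.2 and 19.3% of wild-type HP1a peak bases, 11.6 and 13.3% of wild-type HP1b, 15.4 and 15.0% of HP1a with HP1b knocked down, and 11.9 and 11.5% of HP1b with HP1a knocked down. Fitted without the blocks, 6 bins were higher and 4 lower. The blocks were chosen by the values tested, so fewer lower bins would remain in any case. No bin passed by limma with −log10 p of at least 4 or without the filter (315 and 534 with unadjusted p under 0.05), and without scaling 2778 were higher and 0 lower, with a median of 0.97 against 0.06. Without HP1a replicate 1 there were 274 higher and 213 lower, without replicate 2 270 and 202, without HP1b replicate 1 4 and 16, and without HP1b replicate 2 47 and 114.

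**Figure D5:**
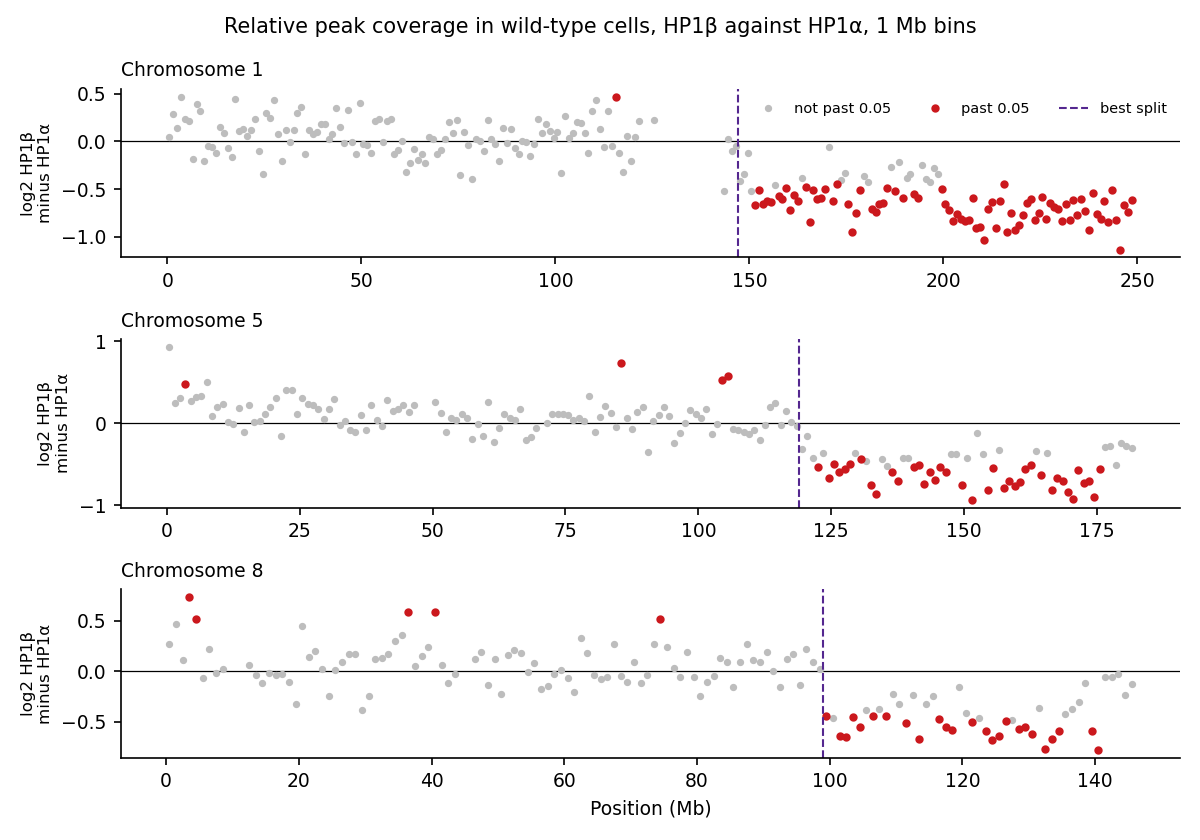
Log2 relative coverage of HP1b minus HP1a in wild type (vertical) in 1 Mb bins along chromosomes 1, 5 and 8 (horizontal, Mb); red dots passed the threshold and the dashed line marks the best single split. The splits, chosen from these same values, lay at 147 Mb of chromosome 1, 119 Mb of chromosome 5 and 99 Mb of chromosome 8. Values stayed lower from there to near the chromosome ends.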

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

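The tests of explanations in this part were chosen after the results were seen, except the one on chance peaks, and the interaction test in bins was planned before.

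The drop from 124811 to 19365 HP1a peaks in the HP1b knockdown was weighed first, as a hypothesis that HP1a occupancy depends on HP1b. Lower read depth was tested by the −log10 p of peaks at the same fold, 3.8 to 4.2, where shallower libraries would have lower values; the knockdown was higher by 0.205 (5.09 against 4.88, spread 0.0456), so depth alone is unlikely. A stricter threshold in the knockdown lists is unlikely too, since with −log10 p of at least 4 in all libraries wild type still had 3.91 times as many peaks. Weaker enrichment in the knockdown immunoprecipitations may be the cause, but the lower fold of the top 19092 peaks (−0.549, from 3.90 to 3.35, spread 0.0969) follows largely from the shorter lists, and the median fold over all listed peaks, 3.37 and 3.32 in the knockdown against 3.29 and 3.26, depends on where each list stops. These values do not separate the explanations, so lower depth, failed enrichment and loss of HP1a upon HP1b knockdown cannot be told apart.

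The higher share of chromosome 19 among HP1a peak bases in the HP1b knockdown was weighed next, as a hypothesis that this chromosome keeps more of its HP1a without HP1b. Chromosome 19 was not alone: shares also rose on chromosomes 22, 16 and 17, among others, and fell on chromosome 1 and some others. The tests below are of chromosome 19 only. If the knockdown lists held just the strongest peaks of an unchanged landscape, the same number of wild-type peaks could show the same share; by fold the knockdown share was still 0.887 points higher (6.99 against 6.10%, spread 0.388), and by −log10 p 1.54 points higher (spread 0.284). Most of the 3.96 points of difference nevertheless went away with the same number of peaks. Chance peaks of single libraries were tested through the share among regions found in both libraries, 10.1% in the knockdown against 4.27%, a difference of 5.83 points with a bootstrap interval of −0.590 to 14.5 (95%, 1000 draws), which leaves chance open as a possible cause. Retention of HP1a by other partners upon knockdown of HP1b stays untested, and zinc finger genes are not enough for it, since those on chromosome 19 went from 0.924 to 1.33% of HP1a peak bases and, with the same number of peaks, their median stood −0.76 from random lists.

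The distal parts of chromosomes 1, 5 and 8 were weighed last. More copies of these segments in the cells may explain the dense peaks: at the same fold, 3.8 to 4.2, the −log10 p was 0.392 higher there than elsewhere (5.66 against 5.27, spread 0.160), and higher in 8 of 8 libraries, as with more reads from more copies. Whether extra copies alone would raise the listed coverage of both proteins alike was not tested. For HP1a itself, peak density here relative to the rest was 3.59 and 3.20 in wild type and 2.44 and 2.37 with HP1b knocked down. The lower HP1b than HP1a share could come from weak peaks near the listing threshold. With −log10 p of at least 4 the difference was −0.16 (spread 0.139), against −0.83 with all peaks, the values that set the splits. Extra copies, weak peaks and a true preference of HP1a for these segments cannot be told apart.

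A difference between both knockdown effects was found in 3 bins (limma, 2 libraries in each of 4 groups). At 169 to 170 Mb of chromosome 5, with SLIT3 and DOCK2, it was −2.07 (log2, SE 0.26, adjusted p 0.0147), where HP1a changed by −1.90 in the HP1b knockdown and HP1b by 0.22 in the HP1a knockdown. At 141 to 142 Mb of chromosome 8, with PTK2, it was 1.55 (adjusted p 0.0382), from 2.22 and 0.64. At 142 to 143 Mb of chromosome 8, with ADGRB1 and ARC, it was 1.81 (adjusted p 0.0147), from 2.72 and 0.88. The change for each protein comes from its own fit, so the parts do not add up exactly to the difference. All 3 lie in the distal blocks.

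Peaks on contigs outside the chromosomes used were left out. They numbered 493 and 416 in wild-type HP1a, 128 and 150 in HP1a with HP1b knocked down, 749 and 760 in wild-type HP1b, and 488 and 802 in HP1b with HP1a knocked down. Fix patches held 325, 252, 63, 39, 574, 573, 320 and 599 of them in that order, and unlocalized sequence 150, 145, 61, 108, 147, 163, 151 and 182.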

How the results depend on the processing

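Alternatives chosen after the data were seen are named above. Groups of 2 libraries allow no other split and no search for extreme libraries, and pairing of replicates is not stated. Where a library was left out, the remaining one of its group was assumed to vary like the others. Regions met and genes lost, kept or gained then rested on that remaining library, so these values change in part by definition. Of 753 values for named genes and bins, 499 kept their size and call, 143 were weaker, 99 stronger, 3 moved and 9 reversed. Of 223 values for gene lists, 153 stayed the same, 48 were weaker and 22 reversed. Values in parentheses are those of the settings used in the results. The cause of these differences was not tested.

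Peaks with −log10 q of at least 5 were so few that limma and the list tests could not be run with them, and peak and covered-base ratios alone are given. The HP1b lists then held 16 and 24 peaks in wild type and 51 and 307 in the HP1a knockdown, so most of them came from knockdown replicate 2. In HP1a after HP1b knockdown, the peak ratio was 0.207 (0.155). It came from 16 and 13 peaks in wild type and 0 and 6 in the knockdown, all of the latter in replicate 2. In HP1b after HP1a knockdown, the peak ratio was 8.95 (0.804), and the covered-base ratio was 7.84 (0.899). Between HP1b and HP1a in wild type, the peak ratio was 1.38 (1.92), and the covered-base ratio was 1.49 (2.42).

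Taking peaks with −log10 q of at least 2 gave the following values. With HP1b knocked down, the peak ratio was 0.0257 (0.155), the covered-base ratio was 0.0224 (0.150), 2.98% of regions (11.5) were met, and 1022 genes (3738) were lost. 8 genes (1723) were kept, 2 genes (54) were gained, 15 bins (209) were higher and 1653 (217) lower, and 2 genes (150) were higher and 861 (2475) lower. 1 list (3) passed by share lost, the share of protocadherin genes lost stood 8.72 points from random (−31.8), the median of zinc finger genes stood −0.49 from random lists (0.58), and the median of zinc finger genes on chromosome 19 stood −0.33 from random lists (0.59). Chromosome 2 from 2 to 3 Mb had a log2 of −1.8 (3.06). With HP1a knocked down, the peak ratio was 2.41 (0.804), the covered-base ratio was 3.38 (0.899), 93 genes (1572) were lost, and 860 genes (7055) were kept. 500 genes (205) were gained, the share of chromosome 19 differed by −0.727 points (1.22), 1 bin (204) was higher and 0 (348) lower by limma with 337 unadjusted, and 2 lists (4) passed by share lost. 1 list (7) passed by median, the median of zinc finger genes stood −0.17 from random lists (0.49), and the median of zinc finger genes on chromosome 19 stood −0.11 from random lists (0.55). In wild type, for HP1b against HP1a, the peak ratio was 1.19 (1.92), the covered-base ratio was 1.69 (2.42), 51.9% of regions (76.1) were met, and 179 genes (117) were lost. 566 genes (7308) were kept, 259 genes (1326) were gained, 0 bins (110) were higher and 0 (155) lower by limma with 194 unadjusted, and 1 list (5) passed by median. The median of protocadherin genes stood 0.0321 from random lists (−0.71), ZIM2 had a log2 of −0.11 (2.11), TBL1X had a log2 of −0.44 (1.79), and NUBPL had a log2 of −0.88 (1.04). By the interaction test, 12 bins (2) were higher and 846 (1) lower.

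Taking peaks with −log10 p of at least 4 in every library gave the following. For HP1a in the HP1b knockdown, the peak ratio was 0.256 (0.155), the covered-base ratio was 0.268 (0.150), 14.5% of regions (11.5) were met, and 1678 genes (3738) were lost. 738 genes (1723) were kept, the share of chromosome 19 differed by 2.38 points (3.96), 7 bins (209) were higher and 0 (217) lower by limma with 665 unadjusted, and 0 genes (150) were higher and 0 (2475) lower by limma with 1614 unadjusted. The median of zinc finger genes stood −0.30 from random lists (0.58), and the median of zinc finger genes on chromosome 19 stood −0.84 from random lists (0.59). For HP1b in the HP1a knockdown, the peak ratio was 1.39 (0.804), the covered-base ratio was 1.8 (0.899), 348 genes (1572) were lost, and 2103 genes (7055) were kept. 347 genes (205) were gained, the share of chromosome 19 differed by −0.933 points (1.22), 93 bins (204) were higher and 67 (348) lower, and 2 lists (4) passed by share lost. 4 lists (7) passed by median, the share of olfactory receptor genes lost stood 4.69 points from random (−14.9), the median of zinc finger genes stood −0.25 from random lists (0.49), and the median of zinc finger genes on chromosome 19 stood −0.42 from random lists (0.55). For HP1b against HP1a in wild type, the peak ratio was 0.883 (1.92), the covered-base ratio was 1.16 (2.42), 47.2% of regions (76.1) were met, and 511 genes (117) were lost. 2163 genes (7308) were kept, 251 genes (1326) were gained, the share of chromosome 19 differed by 1.86 points (0.989), and 0 bins (110) were higher and 0 (155) lower by limma with 315 unadjusted. 2 lists (5) passed by median, and chromosome 19 from 48 to 49 Mb had a log2 of −0.27 (0.85). For the interaction, 0 bins (2) were higher and 0 (1) lower by limma with 372 unadjusted.

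The same number of top peaks from each library gave the following. In HP1a after HP1b knockdown, 24.9% of regions (11.5) were met, 404 genes (3738) were lost, 895 genes (1723) were kept, and 435 genes (54) were gained. The share of chromosome 19 differed by 0.887 points (3.96), 130 bins (209) were higher and 86 (217) lower, 0 genes (150) were higher and 0 (2475) lower by limma with 806 unadjusted, and the median of zinc finger genes stood −0.52 from random lists (0.58). The median of zinc finger genes on chromosome 19 stood −0.76 from random lists (0.59). In HP1b after HP1a knockdown, 341 genes (205) were gained, the share of chromosome 19 differed by 0.906 points (1.22), 2 genes (0) were higher, and 4 lists (7) passed by median. Between HP1b and HP1a in wild type, 54.7% of regions (76.1) were met, 613 genes (117) were lost, 341 genes (1326) were gained, and the share of chromosome 19 differed by 2.35 points (0.989). 233 bins (110) were higher, 2 lists (5) passed by median, and the median of epithelial and basal genes stood 0.0587 from random lists (−0.56). In the interaction, 0 bins (1) were lower by limma with 345 unadjusted.

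Covered bases without scaling to the library total gave the following. With HP1b knocked down, 4 bins (209) were higher and 2736 (217) lower, 51 genes (150) were higher and 4656 (2475) lower, 0 lists (3) passed by median, and the median of zinc finger genes stood −0.00456 from random lists (0.58). The median of zinc finger genes on chromosome 19 stood −0.24 from random lists (0.59). With HP1a knocked down, 49 bins (204) were higher and 51 (348) lower. In wild type, for HP1b against HP1a, 2778 bins (110) were higher and 0 (155) lower by limma with 2780 unadjusted, ESRRG had a log2 of 0.0701 (−1.19), chromosome 1 from 245 to 246 Mb had a log2 of 0.00514 (−1.14), and chromosome 1 from 210 to 211 Mb had a log2 of 0.0481 (−1.04). Chromosome 1 from 176 to 177 Mb had a log2 of 0.0132 (−0.95). By the interaction test, 0 bins (2) were higher and 2504 (1) lower by limma with 2524 unadjusted.

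Fitting every feature without the filter gave the following. For HP1a in the HP1b knockdown, 94 bins (209) were higher and 53 (217) lower, and 0 genes (150) were higher and 0 (2475) lower by limma with 2267 unadjusted. For HP1b in the HP1a knockdown, 38 bins (204) were higher and 6 (348) lower. For HP1b against HP1a in wild type, 0 bins (110) were higher and 0 (155) lower by limma with 534 unadjusted.

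A single fit of all 8 libraries gave the following. In HP1a after HP1b knockdown, 331 bins (209) were higher and 701 (217) lower, and 356 genes (150) were higher. In HP1b after HP1a knockdown, 78 bins (204) were higher and 36 (348) lower, and 66 genes (0) were higher and 189 (0) lower. Between HP1b and HP1a in wild type, 0 bins (110) were higher and 0 (155) lower by limma with 244 unadjusted. A pseudocount multiplied by 4 gave the following. With HP1b knocked down, 327 bins (217) were lower, and 0 genes (150) were higher and 0 (2475) lower by limma with 3338 unadjusted. By the interaction test, 24 bins (2) were higher and 13 (1) lower.

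With a replicate block, which treats libraries of the same number as paired, the values were as follows. For HP1a in the HP1b knockdown, 326 bins (217) were lower, and 19 genes (150) were higher and 0 (2475) lower by limma with 3786 unadjusted. For HP1b in the HP1a knockdown, 338 bins (204) were higher and 657 (348) lower, and 121 genes (0) were higher and 281 (0) lower. For HP1b against HP1a in wild type, 63 bins (110) were higher and 93 (155) lower, and 2 genes (0) were higher and 3 (0) lower.

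Bins of 250 kb gave the following. In HP1a after HP1b knockdown, 1000 bins (217) were lower. In HP1b after HP1a knockdown, 771 bins (204) were higher and 1327 (348) lower. Between HP1b and HP1a in wild type, 1 bin (110) was higher and 13 (155) lower. With at least 50% of a region covered, the regions met were fewer. With HP1b knocked down, 3.68% of regions (11.5) were met. With HP1a knocked down, 42.2% of regions (65.4) were met. In wild type, for HP1b against HP1a, 53.9% of regions (76.1) were met. Fitting without the distal blocks, which were chosen by the HP1b minus HP1a difference itself, changed the bins. For HP1b against HP1a in wild type, 6 bins (110) were higher and 4 (155) lower. Rotating each list along the gene order gave fewer calls. In HP1a after HP1b knockdown, 0 lists (3) passed by median. In HP1b after HP1a knockdown, 2 lists (4) passed by share lost, and the share of olfactory receptor genes lost stood 3.98 points from random (−14.9). Between HP1b and HP1a in wild type, 0 lists (2) passed by share lost, and 2 lists (5) passed by median. Random lists matched on covered bases also gave fewer. With HP1a knocked down, 0 lists (4) passed by share lost. In wild type, for HP1b against HP1a, 0 lists (2) passed by share lost.

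With each library left out in turn (leave-one-out), the lowest and highest values were as follows. For HP1a in the HP1b knockdown, 5.16 to 6.59% of regions (11.5) were met, 4864 to 6053 genes (3738) were lost, 1781 to 3081 genes (1723) were kept, and 112 to 408 genes (54) were gained. 118 to 511 bins (209) were higher and 18 to 1059 (217) lower, 24 to 1054 genes (150) were higher and 2 to 2511 (2475) lower, the median of zinc finger genes stood −0.11 to 1.16 from random lists (0.58), and the median of zinc finger genes on chromosome 19 stood −0.34 to 1.28 from random lists (0.59). For HP1b in the HP1a knockdown, the covered-base ratio was 0.751 to 1.05 (0.899), 42.9 to 55.0% of regions (65.4) were met, 1896 to 3721 genes (1572) were lost, and 353 to 885 genes (205) were gained. 55 to 438 bins (204) were higher and 20 to 839 (348) lower, 72 to 257 genes (0) were higher and 75 to 1753 (0) lower, 4 to 7 lists (4) passed by share lost, and 4 to 7 lists (7) passed by median. For HP1b against HP1a in wild type, 50.6 to 60.8% of regions (76.1) were met, 314 to 611 genes (117) were lost, 2235 to 2883 genes (1326) were gained, and 4 to 274 bins (110) were higher and 16 to 213 (155) lower. 1 to 195 genes (0) were higher and 1 to 172 (0) lower, 0 to 4 lists (5) passed by median, and the median of ribosomal protein genes stood −1.49 to 0.84 from random lists (−1.57). For the interaction, 0 to 329 bins (2) were higher and 0 to 577 (1) lower.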

Other observations

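Apart from CBX1, the genes of this part were picked for mention after their values were seen. LDLRAD3 had less coverage by both proteins in the knockdowns: HP1a went from 5.88 ± 1.48% to none listed in the HP1b knockdown, and HP1b from 13.2 ± 0.0243 to 2.03 ± 0.069% in the HP1a knockdown (SD, n = 2 each, adjusted p 0.024 and 0.141, limma). The bin of MYT1L rose in both comparisons, but for HP1a it turned round with −log10 q of at least 2 (log2 −1.8). SHANK2, in the HP1a bin that kept its coverage at 70 to 71 Mb of chromosome 11, had HP1b over 11.8 ± 1.21% in wild type and 41.0 ± 13.2% in the HP1a knockdown (adjusted p 0.141). CBX1, the gene of HP1b, had HP1b over 4.49 ± 3.51% in wild type and 0.278 ± 0.394% in the HP1a knockdown (adjusted p 0.201). The liver gene CYP2E1, near the end of chromosome 10, was listed at 0 for HP1b in wild type and reached 18.9 ± 18% in the HP1a knockdown (adjusted p 0.141).

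HP1b peaks of the HP1a knockdown were stronger at the same fold: between a fold of 3.8 and 4.2 the median −log10 p was 6.08 and 5.95 in the knockdown against 5.14 and 5.05 in wild type. The number of HP1b peaks in the knockdown was lower with all peaks and 1.39 times higher with −log10 p of at least 4. By this measure, used above for read depth, deeper knockdown libraries may account for the stronger peaks.

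Whether libraries of the same replicate number go together was checked across bins. The correlations were 0.052 for HP1a in the HP1b knockdown, 0.315 for HP1b in the HP1a knockdown and −0.205 for HP1b against HP1a. These are correlations across bins, not across independent replicates. The numbers that name the peaks of a list had gaps in all 8 lists, from 228 to 1312 absent peaks (0.478 to 1.34%), and between 111 and 909 peaks stood out of order. Some peaks lay on fix-patch contigs. How these gaps arose is not given in the sources used here.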
